A study of Mus musculus with 6 samples.

How the data were processed

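Poly(A) RNA of MLE-12 cells was sequenced in 6 libraries, 3 from cells infected with a control adenovirus and 3 from cells infected with a p21-overexpressing adenovirus. Per the labels' protocols, the libraries kept strand by dUTP marking and were read as paired ends on an Illumina NovaSeq; whether the counting used strand is not given in the sources used here. cutadapt, HISAT2 and StringTie are named in the submitters' processing notes without versions, and the genome build is mm10, per the submitters' processing notes. The annotation release is not given in the sources used here.

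The deposited table lists 55385 Ensembl genes with a count and an FPKM value (fragments per kilobase of transcript per 1000000 mapped fragments) for each library, per the file headers. The deposited counts are estimated counts in whole numbers that are not 1 per read pair. In control replicate 1, 347, 1176 and 189 genes had a count of 3, 4 and 5, so that 1 read pair corresponds to about 4 counts and the values were derived from coverage. Counting error is therefore larger than the counts themselves would give, and limits of detection were set at 12 estimated counts, about 3 read pairs, per library. The deposited FPKM values are 0.0001 wherever the count is 0. Of the gene identifiers, 55144 are in GENCODE M21, and 94.3% of these have the same position there. Gene symbols and positions are those of the deposited table.

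Groups and replicate numbers were taken from the sample titles. The design fixed before the data were examined named limma on log2(FPKM + 1) and, should the table hold raw counts, edgeR. The table holds estimated counts, which are not raw counts. Making edgeR the main test and limma an alternative therefore departed from that design. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with filterByExpr, TMM scaling and no covariate. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. filterByExpr left 18709 genes, which hold 99.96% of all counts, out of 28666 with a count in any library. The biological coefficient of variation was 33.4%. Normalised counts per 1000000 (CPM) use the TMM-scaled library sizes, and each standard error is the log2 fold change divided by the square root of the F statistic. Library shares were compared with an exact permutation test.

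Total estimated counts ranged from 57376180 to 75049177 per library. Replicates of a group differed with a chi-square per degree of freedom of 16.5 to 56.0 on counts divided by 4. On that scale 1 count is about 1 read pair, and counting error alone gives about 1. This says only that no library is a second sequencing of another. On simulated counts of the 18709 genes, 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold. The same test recovered 4.48%, 28.4% and 68.2% of them, with 3 unchanged genes among 70 called. The real data gave 1847 calls, so the adjusted threshold was stricter in the simulation. These shares can therefore understate recovery in the real data.

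The 25 gene lists were fixed before the data were examined. They cover inhibitors of cyclin-dependent kinases, G1/S and G2/M genes, repair, p53 targets, senescence-associated secreted factors, lysosome, 4 lung epithelial states, mesenchyme, TGF-beta, leukocytes, endothelium, interferon, NF-kappaB, cholesterol, unfolded protein response, NRF2, cell death, hypoxia, histones, mitochondrial transcripts and ribosomal proteins. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 25 lists, beside camera with an estimated correlation and fry. Cdkn1a was left out of the list of inhibitors because it was introduced.

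Named genes follow a rule fixed before the data were examined. It takes Cdkn1a, the 6 largest rises and 6 largest falls among genes past the threshold with library ranges apart, leaving out model names, and from each list the 2 members with the largest change, or the largest of each direction. Headed lists give up to 2 further members, and a list with none past the threshold gives the member with the highest FPKM. The 8 largest rises and falls at a mean FPKM of at least 1, and further list members given with their log2 fold change in parentheses or singled out in a count, were chosen after their values were seen. A few genes that the rule takes, or that list counts include, are not reported here by name. Alternatives were other tests (limma on FPKM, DESeq2 1.42.0), scalings, pseudocounts, filters, a replicate block, a minimum fold change, summed symbols and leaving out each library in turn. DESeq2, scaling to total counts, the robust fit and counts divided by 4 were added after the data were seen, as were the tests of KEGG pathways as annotated in the deposited table.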

Results

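Gene expression was measured in MLE-12 cells, an immortalised mouse lung epithelial line with features of alveolar type 2 cells, the surfactant-producing cells of the alveolus. Poly(A) RNA was sequenced from 3 libraries of cells that had received an adenovirus overexpressing p21 and from 3 libraries of cells that had received a control adenovirus. p21 is the product of Cdkn1a and inhibits cyclin-dependent kinases, which drive cells through the division cycle. The comparison asks which transcripts differed between p21-overexpressing and control cells. Total estimated counts were 74882145, 59084753 and 57376180 in control replicates 1 to 3 and 64230038, 75049177 and 73834093 in p21 replicates 1 to 3, at about 4 counts per read pair. Between 12079 and 12466 genes reached 1 FPKM in a library. Pearson correlations of log2 expression across genes, which are not independent replicates, were 0.962 to 0.972 within groups and 0.945 to 0.954 between groups. The first principal component held 37.4% of the variance and separated the groups, and the second, with 19.6%, set p21 replicate 1 (62.0) apart from p21 replicates 2 and 3 (-25.6 and -32.2) and control replicate 2 (-54.2) apart from control replicates 1 and 3 (34.2 and 15.8). The labels call the samples triplicates without saying that the cultures were separate, so p-values measure only the spread between these samples, which may be technical.

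Cdkn1a, the overexpressed gene, was 16.1-fold higher in p21 cells. Its level rose from 81.9 ± 2.49 to 1319 ± 167 normalised counts per 1000000 (CPM, mean ± SD, n = 3 per group), with a log2 fold change of 4.01 ± 0.138 (SE) and an edgeR adjusted p of 4.84e-05. The 3 control libraries held 79.1, 84.0 and 82.5 CPM, and the 3 p21 libraries held 1505, 1271 and 1180 CPM. The gene (ENSMUSG00000023067) lies on the plus strand of mouse chromosome 17 from 29090976 to 29100727 (mm10). The value can mix transcripts of the vector with those of the cell's own gene. The labels speak both of adenovirus infection and of stable transfection, and the species of the p21 insert, the vector dose and the time after infection are not given in the sources used here. Among the 6 other inhibitors of cyclin-dependent kinases, the INK4 family member Cdkn2d fell, from 23.9 ± 2.75 to 13.6 ± 3.12 CPM (n = 3, edgeR adjusted p = 0.0466), and 5 did not pass. Cdkn2d did not pass in any of the 6 fits without 1 library, nor without a filter or with the replicate block. Those 6 genes did not stand apart as a list (camera adjusted p = 0.305).

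**Figure D1:**
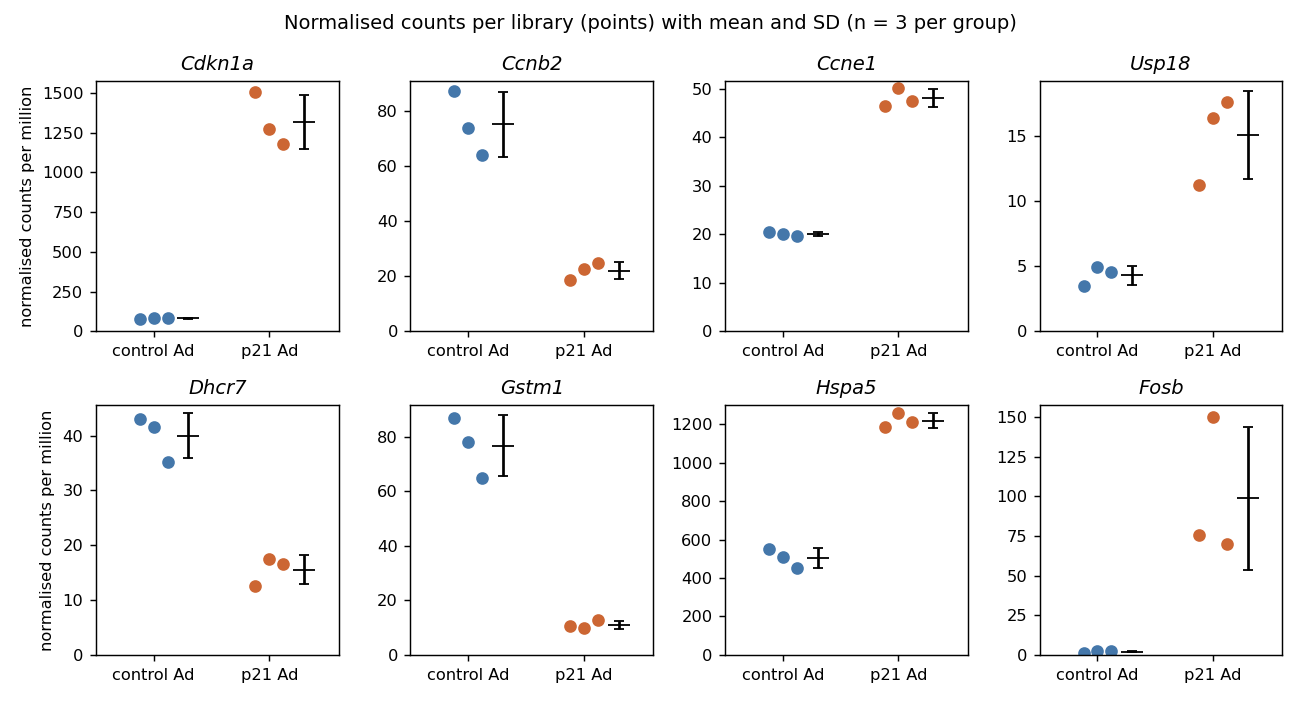
Normalised counts in CPM in each library (points, 3 per group) for 8 genes, with the group mean and SD (black); every vertical axis starts at 0. Cdkn1a was at 1180 CPM or more in each p21 library and at 84.0 CPM or less in each control library.

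Across the 18709 genes tested, 883 were higher and 964 lower in p21 cells at an adjusted p under 0.05 (edgeR), which is 9.87% of the genes. Of these, 443 higher and 438 lower genes had an absolute log2 fold change of at least 1. Cdkn1a had the smallest adjusted p. In each of the 1847 genes the range of the p21 libraries lay apart from that of the control libraries. This held for 34.3% of all tested genes, where chance gives 10%. The total of 1847 fell to 525 without control replicate 2, 756 without control replicate 3, 1205 without p21 replicate 1, 539 without p21 replicate 2 and 341 without p21 replicate 3. Of 25 gene lists fixed before the data were examined, 12 passed camera with a preset correlation between genes, 3 as higher and 9 as lower, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.179. At an unadjusted p under 0.05 the estimated correlation left 3 lists, the interferon, unfolded protein and G2/M lists, and fry, which asks whether a list's genes move one way, called 8 lists, the interferon, unfolded protein, G2/M, cholesterol, NRF2, mitochondrial, p53 target and TGF-beta lists. Camera with the preset correlation also called 5 to 16 lists in the 9 other ways of parting the 6 libraries into 3 against 3, so its list calls are weak evidence. Each of those ways mixes the groups unevenly and keeps part of their difference, so none stands for chance alone.

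**Figure D2:**
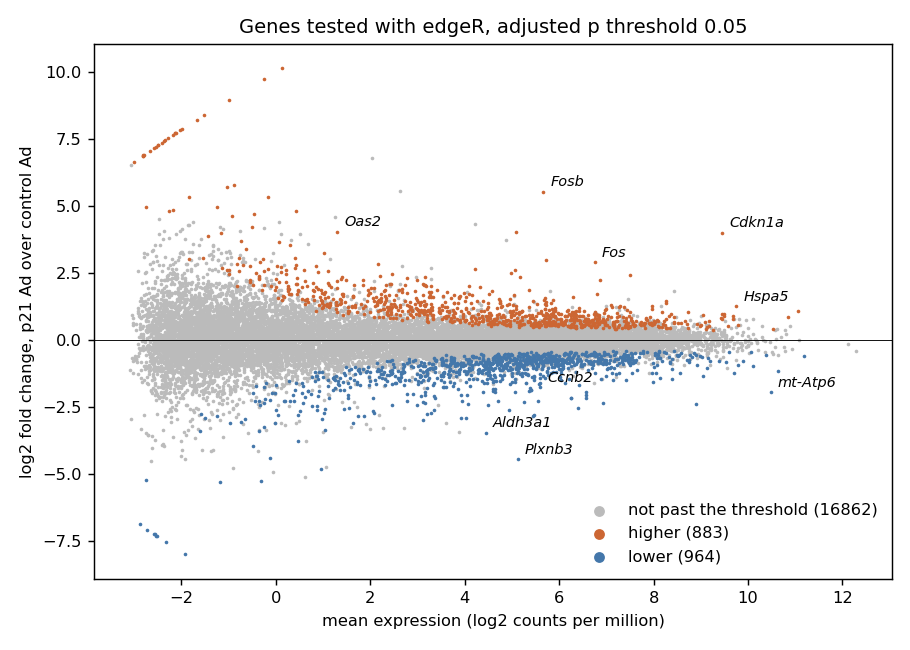
Log2 fold change of p21 over control cells (vertical axis) against mean expression in log2 CPM (horizontal axis), with 1 point for each of the 18709 genes tested. Genes past an adjusted p of 0.05 in edgeR are coloured by direction, 883 higher and 964 lower; the diagonal band of points at low expression and high fold change holds genes with no counts in control libraries.

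Genes of G2 phase and mitosis were lower in p21 cells, while cyclin E genes of the step from G1 into S phase were higher. Ccnb2, a cyclin B that partners Cdk1 for entry into mitosis, fell 3.41-fold, from 75.2 ± 11.7 to 22.0 ± 3.17 CPM (n = 3, edgeR adjusted p = 0.00282). The centromere protein gene Cenpf fell 2.27-fold, the spindle gene Psrc1 2.13-fold and Sgo2a, which protects cohesion at centromeres, 2.12-fold. Of 71 G2/M genes, 19 fell and 52 did not pass, with 28 lower adjusted over the list alone. Members named after their values were seen are the kinases Aurka and Aurkb, with log2 fold changes of -0.63 and -0.99, and Birc5, at -0.60. Mki67 (-0.40, adjusted p = 0.509), Cdk1 (-0.28, adjusted p = 0.315) and Top2a (-0.07, adjusted p = 0.810 in edgeR) did not pass. The list median was -0.37 on the log2 scale (camera adjusted p = 8.28e-11, and adjusted p = 0.294 with an estimated correlation). Without p21 replicate 3, p21 replicate 2, control replicate 2 or control replicate 3, 1, 4, 6 and 8 members passed as lower.

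Ccne1, which encodes cyclin E1, rose 2.40-fold, from 20.02 ± 0.377 to 48.0 ± 1.86 CPM (n = 3, edgeR adjusted p = 0.00265), and Ccne2 rose 1.97-fold. Cdc25a, a phosphatase that activates cyclin-dependent kinases, rose 1.61-fold. Of 50 G1/S and replication genes, 5 rose, 3 fell and 42 did not pass, with 6 higher and 3 lower adjusted over the list alone. Rrm2 and Mcm2, with log2 fold changes of 0.60 and 0.52, rose. Dscc1, part of a clamp loader for replication, fell 1.96-fold, and Rfc5 and Chaf1b, at -0.62 and -0.51, also fell. The median over the list was 0.09 (camera adjusted p = 0.0379, and adjusted p = 0.541 with an estimated correlation). That call ended without control replicate 1 (adjusted p = 0.164) or p21 replicate 2 (adjusted p = 0.0879), and 2 members passed as higher without control replicate 2 or 3 or p21 replicate 2 or 3, with 1 or fewer as lower there and without p21 replicate 1. A test of the G2/M list against the G1/S list was not named in the design fixed in advance. In it the G2/M list was lower (unadjusted camera p = 2.19e-12, and p = 0.0112 with an estimated correlation, 121 genes). None of the 37 homologous recombination and Fanconi repair genes passed in edgeR, 8 had an unadjusted p under 0.05, and DESeq2 called 1 of them lower (camera adjusted p = 0.355, and 0.0296 as lower without control replicate 1). Nbn, the member with the highest FPKM, was at 93.2 ± 21.3 and 85.7 ± 7.65 CPM (n = 3). Of 18 replication histone genes, whose transcripts mostly lack a poly(A) tail, 0 passed in edgeR, 3 had an unadjusted p under 0.05 and DESeq2 called 0 (camera adjusted p = 0.582); H1f2 was at 7.99 ± 1.48 and 11.1 ± 1.34 CPM.

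Interferon-stimulated genes were higher in p21 cells. Oas2, an antiviral enzyme that senses double-stranded RNA, rose from near the detection limit, from 0.276 ± 0.126 to 4.57 ± 1.19 CPM (n = 3, edgeR adjusted p = 0.00372). Xaf1 rose 3.60-fold, the antiviral GTPase Mx2 3.56-fold, and Usp18, which removes Isg15 from proteins, 3.50-fold, from 4.31 ± 0.726 to 15.1 ± 3.41 CPM. Of 51 interferon-stimulated genes, 24 rose and 27 did not pass, with 33 higher adjusted over the list alone. The risers include, named after their values were seen, the transcription factors Stat2 (1.53), Irf7 (1.62) and Irf9 (1.29), and Isg15 (1.76). The list members B2m (0.97), Tap1 (1.06) and H2-D1 (1.09), named the same way, also rose. Ifit1 (1.30, adjusted p = 0.0709), Rsad2 (1.12, adjusted p = 0.229) and Cxcl10 (0.18, adjusted p = 0.809 in edgeR) did not pass. The list median was 0.97 (camera adjusted p = 1.91e-17, and adjusted p = 0.179 with an estimated correlation). The log2 fold changes of Xaf1 and Mx2, 1.85 and 1.83, came as near 0 as 1.153 and 0.91 over the alternatives, of which 1 of 24 lost Mx2. Without p21 replicate 2 or 3, 15 and 12 members passed as higher, and H2-D1, the Gbp genes, Irgm1 and Igtp have close relatives with which reads can be shared.

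Genes of cholesterol synthesis were lower in p21 cells. Dhcr7, an enzyme of the last steps of cholesterol synthesis, fell 2.57-fold, from 39.9 ± 4.10 to 15.5 ± 2.62 CPM (n = 3, edgeR adjusted p = 0.00629). Fdps, which makes farnesyl diphosphate, fell 2.55-fold, from 72.0 ± 8.60 to 28.3 ± 3.89 CPM. Of 24 genes, 14 fell and 10 did not pass, with 14 lower adjusted over the list alone. Srebf2, the transcription factor of this pathway, was among them at -0.90, a member named after its value was seen. As a list they had a median of -0.72 (camera adjusted p = 4.77e-08, and adjusted p = 0.349 with an estimated correlation). Members passing as lower numbered 7 without control replicate 1 and 6 without each of the other 5 libraries in turn.

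Antioxidant and detoxification genes regulated by the transcription factor NRF2 were lower in p21 cells. Aldh3a1, an aldehyde dehydrogenase, fell 11-fold, from 39.9 ± 17.3 to 3.62 ± 0.230 CPM (n = 3, edgeR adjusted p = 0.00246). The glutathione transferases Gstm1 and Gsta4 fell 6.94-fold and 4.87-fold; reads of these can be shared with other members of their families. Of 25 genes, 11 fell, 1 rose and 13 did not pass, with 17 lower and 1 higher adjusted over the list alone. Nqo1 (-2.27), Srxn1 (-2.15), Gsr (-0.92) and Cat (-0.76), named after their values were seen, were among the falls. Tkt, an enzyme of the pentose phosphate pathway, rose 1.72-fold. Hmox1 (0.21, edgeR adjusted p = 0.281) did not pass. The list median was -0.66 (camera adjusted p = 5.94e-08, and adjusted p = 0.473 with an estimated correlation). Without control replicates 1, 2 or 3, 6, 4 and 5 members passed as lower, and without p21 replicates 1, 2 or 3, 5, 4 and 4. Tkt did not pass without control replicate 2 or 3 or p21 replicate 2 or 3, and Aldh3a1 came as near 0 as -2.765 on the log2 scale over the alternatives.

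Genes of the unfolded protein response were higher in p21 cells. Hspa5, the main chaperone of the endoplasmic reticulum, rose 2.41-fold, from 505.5 ± 50.6 to 1219 ± 39.6 CPM (n = 3, edgeR adjusted p = 0.00264). The co-chaperone gene Dnajb9 rose 2.48-fold, and Ppp1r15a, which directs dephosphorylation of eIF2alpha, rose 2.41-fold. Of 30 genes, 6 rose, 1 fell and 23 did not pass, with 10 higher and 1 lower adjusted over the list alone. Dnajc3, Vldlr and Sel1l were the other risers, with log2 fold changes of 0.73, 1.00 and 0.46, and Pdia4, a protein disulfide isomerase, fell 1.42-fold. Over the whole list the median was 0.47 (camera adjusted p = 2.45e-06, and adjusted p = 0.179 with an estimated correlation). Without control replicate 2, p21 replicate 2 or p21 replicate 3, 3, 3 and 2 members passed as higher, and without control replicate 1, 9 did. Pdia4 did not pass in any of the 6 fits without 1 library.

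Mitochondrially encoded transcripts were lower in p21 cells. That list was fixed as a sign of RNA quality and library make-up, so a technical difference between the groups can also give this result. Such a difference was not tested. mt-Nd1, a subunit of complex I, fell 2.24-fold, from 2193 ± 122 to 977 ± 246 CPM (n = 3, edgeR adjusted p = 0.0125), and mt-Nd2 fell 1.91-fold. mt-Cytb fell 1.5-fold and passed in 12 of 25 alternatives. mt-Atp6, which overlaps mt-Atp8, fell 3.86-fold, from 2273 ± 745 to 588 ± 379 CPM, with p21 replicate 1 at 1026 CPM and p21 replicates 2 and 3 at 382 and 358 CPM. It passed in 18 of 25 alternatives, with log2 fold changes of -2.619 to -1.655. Of 13 genes, 6 fell and 7 did not pass, with 9 lower adjusted over the list alone (median -0.56, camera adjusted p = 1.99e-06, and adjusted p = 0.349 with an estimated correlation). The share of all counts on the mitochondrial chromosome, genes outside the 13 included, was 2.29% ± 0.345 in control and 1.47% ± 0.193 in p21 libraries (n = 3). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. The share of long noncoding RNA was 0.555% ± 0.0533 and 0.680% ± 0.134, with p21 replicate 1 at 0.834%. Without control replicates 1, 2 or 3, 3, 2 and 2 members passed as lower, and without p21 replicates 2 or 3, 2 and 1. limma on log2(FPKM + 1) called 3 of the 13, and after quantile normalisation limma called 2, with a list median of -0.226. Of 50 ribosomal protein genes, Rpl30 rose 1.63-fold, Rpl14 fell 1.80-fold and 48 did not pass (camera adjusted p = 0.343); their share of counts was 1.91% in p21 replicate 1 and 2.97% and 2.73% in p21 replicates 2 and 3. Without p21 replicate 1 that list was called higher (camera adjusted p = 0.0124), and without p21 replicate 2 it was called lower (camera adjusted p = 0.00786). Without control replicate 2 or 3 or p21 replicate 2 or 3, 0 ribosomal protein genes passed in either direction.

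Several secreted factors of the senescence-associated secretory phenotype were lower in p21 cells. Ccl2, a monocyte chemokine, fell 7.64-fold, from 26.7 ± 11.5 to 3.49 ± 1.01 CPM (n = 3, edgeR adjusted p = 0.00747). Igfbp5, which binds insulin-like growth factors, fell 4.81-fold, and the cytokine gene Il18 fell from 0.874 ± 0.208 to 0.0997 ± 0.0417 CPM, with fewer than 12 estimated counts in each p21 library. The chemokine Cxcl16 rose 1.61-fold and kept that call in 1 of the 6 fits without 1 library, that without p21 replicate 1; Il18 passed in 10 of 15 alternatives. Of 49 genes, 7 fell, 1 rose and 41 did not pass, with 7 lower and 2 higher adjusted over the list alone. Plau, Mmp2 and Igfbp6 were also among the falls, and Il6, at 7.39 and 11.04 CPM, did not pass (edgeR adjusted p = 0.464). The list median was -0.13 (camera adjusted p = 0.0329, and adjusted p = 0.511 with an estimated correlation). Camera's call ended without control replicate 2, control replicate 3, p21 replicate 1 or p21 replicate 2 (adjusted p = 0.0855, 0.0674, 0.0797 and 0.0882), and 3 members passed as lower without p21 replicate 3 and 4 without p21 replicate 2. Of 30 NF-kappaB target genes, 5 fell and 25 did not pass, with 5 lower adjusted over the list alone (median -0.26, camera adjusted p = 0.00321, and adjusted p = 0.511 with an estimated correlation). Bcl2l1, which encodes the survival protein BCL-XL, fell 2.99-fold, Zc3h12a 1.91-fold and Tnip1 1.88-fold; Vcam1 (-0.46) also fell. That list's call ended without control replicate 2 (adjusted p = 0.0620), and 8, 3, 3 and 1 members passed as lower without control replicate 1, control replicate 2, p21 replicate 2 and p21 replicate 3.

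Markers of several lung epithelial states were lower in p21 cells, with exceptions in most lists. Foxa2, a transcription factor of lung epithelium, fell 2.78-fold, from 64.6 ± 6.92 to 23.2 ± 2.61 CPM (n = 3, edgeR adjusted p = 0.00308). Lgi3 fell 7.96-fold and the protease gene Ctsh 2.68-fold, while the transcription factor gene Cebpa rose 1.95-fold. Cebpa kept its call in 1 of the 6 fits without 1 library, that without p21 replicate 1, and Lgi3, at -2.99 on the log2 scale, came as near 0 as -1.602 over the alternatives. Of 22 alveolar type 2 markers, 4 fell, 1 rose and 17 did not pass, with 4 lower and 1 higher adjusted over the list alone (median -0.46, camera adjusted p = 0.00937, and adjusted p = 0.473 with an estimated correlation). Abca3 (-0.46) also fell, and the surfactant genes Sftpc (-1.12, adjusted p = 0.318) and Sftpb (-0.55, adjusted p = 0.260 in edgeR) did not pass. Of 25 alveolar type 1 markers, 4 fell and 21 did not pass, with 5 lower and 1 higher adjusted over the list alone (median -0.28, camera adjusted p = 0.00878, and adjusted p = 0.473 with an estimated correlation). These were Krt7 (3.20-fold lower), Rtkn2 (2.56-fold), Hopx (2.08-fold) and Cryab (2.07-fold). The type 2 call ended without p21 replicate 1 or 2 (adjusted p = 0.0564 and 0.0771) and the type 1 call without control replicate 1 (adjusted p = 0.0665); 2 type 1 markers passed as lower without each control library in turn and 1 without p21 replicate 3.

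Of 28 markers of the Krt8-high transitional alveolar state, 10 fell, 3 rose and 15 did not pass, with 13 lower and 5 higher adjusted over the list alone. Krt8, a keratin of simple epithelia, fell 4.55-fold, from 154.8 ± 103 to 34.0 ± 0.700 CPM (n = 3, edgeR adjusted p = 0.0189), with control replicate 1 at 273 CPM and control replicates 2 and 3 at 99.2 and 92.1 CPM. Ccnd1, which encodes cyclin D1, fell 2.35-fold and Tnip3 3.26-fold, and the stress gene Ndrg1 rose 2.57-fold. Sprr1a (1.11) and Fn1 (0.91) were the other risers. Across all members the median was -0.48 (camera adjusted p = 0.0187, and adjusted p = 0.473 with an estimated correlation), and camera did not call it with limma on log2(FPKM + 1) (adjusted p = 0.105). Without control replicates 1, 2 or 3, 6, 4 and 6 members passed as lower, and without p21 replicates 1, 2 or 3, 5, 3 and 2. Over the alternatives Krt8 and Tnip3, at -2.19 and -1.71 on the log2 scale, came as near 0 as -1.476 and -0.8056. Of 12 airway markers, 4 fell, 1 rose and 7 did not pass, with 5 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0792, and 0.0473 and 0.0203 as lower without p21 replicate 1 or 3). The mucin gene Muc5b fell 4.54-fold and Krt14 2.93-fold, while Ngfr rose 2.57-fold. Trp63, a basal cell transcription factor, fell from 1.38 ± 0.582 to 0.128 ± 0.0342 CPM (n = 3), with fewer than 12 estimated counts in each p21 library. Airway markers passing as lower numbered 2 or fewer without control replicate 2 or 3 or p21 replicate 2 or 3, and Krt14 passed in 14 of 24 alternatives.

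**Figure D3:**
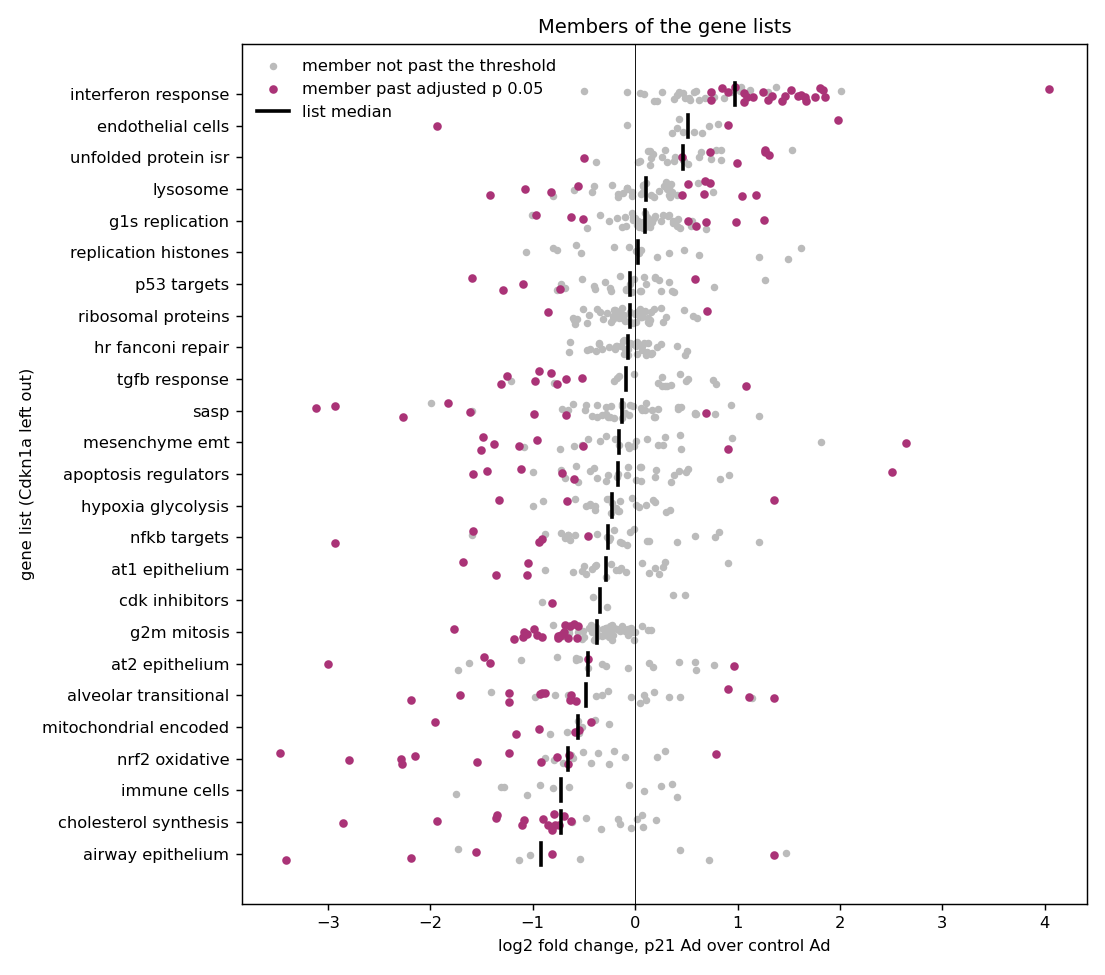
Log2 fold change of p21 over control cells (horizontal axis) for the members of the 25 gene lists (vertical axis, ordered by median; Cdkn1a left out). Grey points did not pass and purple points passed an adjusted p of 0.05 in edgeR, and black lines mark list medians; the median was 0.97 for interferon-stimulated genes.

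Matrix and growth factor genes moved in both directions. Dcn, which encodes the matrix proteoglycan decorin, fell 2.79-fold, from 250.5 ± 9.57 to 89.7 ± 3.77 CPM (n = 3, edgeR adjusted p = 0.00118), Col6a1 fell 2.60-fold and S100a4 2.84-fold. Col5a1 rose from near the detection limit, from 0.236 ± 0.0703 to 1.49 ± 0.124 CPM. Of 29 mesenchymal genes, 6 fell, 2 rose and 21 did not pass, with 7 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0954, 0.0119 as lower without p21 replicate 1 and 0.0438 at a mean FPKM of at least 0.1). Tgfb1 rose 2.12-fold, from 20.9 ± 2.14 to 44.3 ± 4.83 CPM (n = 3, edgeR adjusted p = 0.00786), whereas the targets of BMP signalling Id1, Id2 and Id3 fell 2.48-fold, 2.38-fold and 1.96-fold. Of 26 TGF-beta response genes, 8 fell, 1 rose and 17 did not pass, with 9 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.376). The endothelial genes Vwf and Flt1 rose 3.96-fold and 1.88-fold, Tek fell 3.83-fold, and 9 of 12 did not pass, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.127); without control replicate 2 or p21 replicate 3, 0 endothelial genes passed as higher, and Vwf passed in 8 of 14 alternatives. Of 12 leukocyte markers, 0 passed in edgeR, 1 had an unadjusted p under 0.05 and DESeq2 called 0 (camera adjusted p = 0.305); Cd68 was at 2.52 ± 0.307 and 3.22 ± 0.867 CPM. Without control replicate 2, p21 replicate 2 or p21 replicate 3, 2, 2 and 1 mesenchymal and 3, 2 and 1 TGF-beta response genes passed as lower, and without control replicate 3, 3 TGF-beta response genes did. As higher, 4 TGF-beta response genes passed without control replicate 1. Of the mesenchymal genes, 1 passed as higher without each control library in turn and 0 without p21 replicate 3. S100a4 passed in 15 of 24 alternatives, Col6a1 in 11 of 15, and Tek, at -1.94, came as near 0 as -1.094.

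Some genes of cell death and of the p53 response changed, and camera called neither list. Hrk, a pro-apoptotic member of the BCL2 family, rose 5.70-fold, from 9.39 ± 4.44 to 53.5 ± 2.48 CPM (n = 3, edgeR adjusted p = 0.00926). Bok fell 2.72-fold and Casp6 2.16-fold, and Casp8 (-0.71) also fell. Of 33 BCL2-family and caspase genes, 5 fell, 1 rose and 27 did not pass, with 6 lower and 5 higher adjusted over the list alone (camera adjusted p = 0.332). That balance depended on the scaling: limma on TPM called 3 higher and 3 lower, and limma on log2(FPKM + 1) called 1 higher and 4 lower. Of 33 p53 targets other than Cdkn1a, 4 fell, 1 rose and 28 did not pass, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.350). Eda2r fell 3.01-fold, Dcxr 2.45-fold, Psrc1 2.13-fold and Ccng1 (-0.74) also fell, while Trp53inp1 rose 1.5-fold; Mdm2 (0.09, adjusted p = 0.799) and Bax (0.05, adjusted p = 0.921 in edgeR) did not pass. Among 43 lysosomal genes, 7 rose, 4 fell and 32 did not pass, with 11 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.134, called higher with limma on TPM at 0.0293, after quantile normalisation at 0.0437, without control replicate 1 at 0.0247 and without p21 replicate 1 at 0.00710). Idua and Ctsl rose 2.26-fold and 2.07-fold, Gusb fell 2.10-fold, and Glb1, which encodes the lysosomal beta-galactosidase, was at 74.6 and 78.5 CPM (edgeR adjusted p = 0.756). Of 27 hypoxia and glycolysis genes, 1 rose (Ndrg1), 2 fell (Slc16a3, 2.52-fold, and Gpi1, 1.58-fold) and 24 did not pass, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.111, and 0.0239 as lower without control replicate 3, where 1 member passed as lower; in the other 5 fits without 1 library 0 did, and Slc16a3 passed in 8 of 24 alternatives). Without control replicate 2, p21 replicate 2 or p21 replicate 3, 1 p53 target each and 1 or fewer genes of cell death passed as lower, and 1 or fewer lysosomal genes as higher, as did lysosomal genes without control replicate 3; without control replicate 1, control replicate 3 or p21 replicate 1, 3 genes of cell death passed as lower. Lysosomal genes passing as lower numbered 2 without control replicate 2 and 1 without p21 replicate 3, and 9 passed as higher without p21 replicate 1. Trp53inp1 did not pass without control replicate 2 or 3 or p21 replicate 2 or 3. Casp6 passed in 8 of 15 alternatives, Bok in 16 of 25, Dcxr in 17 of 24 and Gpi1 in 16 of 25.

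The largest fold changes by the rule fixed in advance fell on genes near the detection limit. Tmem92 was at 0.934 ± 0.133 CPM in p21 cells (n = 3) and at 0 in each control library, at least 4.89-fold higher against a floor of 12 estimated counts per library. Lsmem1, Rhcg, Slc3a1, Usp17ld and Prok1 were likewise at 0 in control libraries and at least 2.27-fold, 2.21-fold, 2.04-fold, 1.96-fold and 1.68-fold higher. Atp13a5, Pipox, Tm4sf4, Gdf6, Tox2 and Rp1 were at 0 in p21 libraries and at least 2.06-fold, 1.74-fold, 1.68-fold, 1.64-fold, 1.49-fold and 1.29-fold lower. Tmem92 passed in 14 of 15 alternatives and the other 11 genes in 5 to 7 of 13 each. By a rule chosen after the values were seen, a mean of at least 1 FPKM, Fosb, a subunit of the AP-1 transcription factor, had the largest rise in edgeR, 46.5-fold, from 2.13 ± 0.563 to 98.7 ± 44.8 CPM (n = 3, edgeR adjusted p = 0.00118). Its log2 fold change, 5.54, was 3.455 with limma on log2(FPKM + 1), below that of Cdkn1a there. Fos, of the same family, rose 7.5-fold, the glycosyltransferase B4galnt2 7.88-fold, the cytokine Il17f 7.23-fold, Akr1b7 6.73-fold, the interferon-inducible GTPase Irgm2 6.36-fold and Lhfpl2 6.08-fold. Akr1b7 had 59, 16 and 16 estimated counts in control libraries, and its log2 fold change of 2.75 ranged from 1.23 to 3.508 over 24 alternatives, of which 5 lost the threshold. Sectm1a fell from 3.71 ± 0.672 CPM to 15, 0 and 12 estimated counts in the p21 libraries, and the semaphorin receptor gene Plxnb3 fell 22.0-fold, from 66.5 ± 11 to 3.03 ± 0.624 CPM (edgeR adjusted p = 0.000508). Upk1b fell 8.60-fold, and the mitochondrial tRNA genes mt-Tl2 and mt-Tm fell from 1.69 ± 0.622 and 1.03 ± 0.0603 CPM to fewer than 12 estimated counts in each p21 library; Aldh3a1, Lgi3 and Ccl2 completed the 8 largest falls by fitted value. Over the alternatives the log2 fold changes of Il17f, Irgm2, Lhfpl2, Plxnb3 and Upk1b came as near 0 as 1.598, 2.00, 1.839, -2.814 and -1.379.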

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

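DESeq2, scaling to total counts, the robust fit and counts divided by 4 were chosen after the data were seen. Cdkn1a stayed past the threshold in every alternative, with log2 fold changes of 3.91 to 4.09. The total of 1847 genes (883 higher, 964 lower) was 1226 (543 higher, 683 lower) when edgeR tested only genes with a mean FPKM of at least 5, 881 (443 and 438) with an absolute log2 fold change of at least 1, and 3023 (1486 and 1537) with DESeq2, which called all 1847. The cause of the difference between the tools was not tested. limma on log2(FPKM + 1) called 1698 genes and shared 1415 with edgeR. With 1 library left out the total ranged from 341 without p21 replicate 3 to 1347 without control replicate 1, with 163 to 683 higher and 178 to 664 lower; these fits have fewer samples. Whether the replicate numbers pair the samples is not given in the sources used here. Deviations from the group means correlated at 0.0377, 0.0538 and -0.0248 across genes for the 3 same-numbered pairs. Not every sample correlated best with its own number. These values cannot decide whether the cultures were paired, and the main test did not use the numbers as pairs. With the replicate number as a block, edgeR called 479 genes, 233 higher and 246 lower. The share of higher genes was 47.8% and ranged from 42.2% to 54.2% over the scalings and pseudocounts. Of the 25 lists, camera called 12, fry 8, and camera with an estimated correlation 0; fits without 1 library called 10 to 14. The G2/M, interferon, cholesterol, unfolded protein, NRF2 and mitochondrial lists stayed past the threshold in all 24 alternative fits with the preset correlation. The transitional alveolar list ended in 7 of them (adjusted p = 0.0749 to 0.105), and the cause was not tested. Lists not called in the full data gained a call in some fits: lysosome in 4 (0.00710 to 0.0437), airway and mesenchyme in 2 each, and repair and hypoxia in 1 each. Of 25 NRF2 genes, 11 of which fell in the main test, 5 fell without a filter. The ribosomal protein list, not called in the full data, had adjusted p-values of 0.00786 to 0.775 without 1 library and turned to higher, with 0.0124, without p21 replicate 1. Nbn, also not called, ranged from -0.28 to 0.011 without 1 library and turned sign without control replicate 2; the cause was not tested. Of the 103 named genes, values without 1 library lost the threshold in 242 of 618 cases, the replicate block in 55 of 103 and other settings in 41 of 1569, with directions kept apart from Nbn. With 3 libraries per group, simulated changes of 1.5-fold were mostly missed, with 4.48% recovered. That simulation called 70 genes against 1847 here, so its adjusted threshold was stricter and the share can understate recovery in the real data.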

Other observations

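The KEGG pathways, the immediate-early gene list and the test of leukocyte markers were chosen after the results were seen. Of 302 KEGG pathways annotated in the deposited table, 9 passed camera with a preset correlation, 1 as higher and 8 as lower, and 0 passed with an estimated correlation, where each of the 9 had an adjusted p of 0.944. Most of the lower pathways share the falling glutathione transferases Gstm1, Gstm6, Gstm7, Gsta3, Gsta4, Gstt1 and Mgst3, so they are not separate findings. These are the pathways of cytochrome P450, chemical carcinogenesis, platinum drug resistance, other drug enzymes and glutathione. Xenobiotic metabolism by cytochrome P450 was lower, with 11 of 34 genes falling and 1 rising (camera adjusted p = 2.34e-06). Its falls include the glutathione transferases Gstm6 (-3.26), Gstm7 (-2.58) and Gstt1 (-1.48), the epoxide hydrolase Ephx1 (-0.94) and the aldehyde dehydrogenase Aldh3b1 (-1.21), while the alcohol dehydrogenase Adh1 rose (1.32, log2 fold changes). Glycolysis and gluconeogenesis was lower, with 9 of 47 genes falling and 2 rising (camera adjusted p = 0.0475). Its falls include the aldehyde dehydrogenases Aldh3a1 (-3.46), Aldh3b1 (-1.21), Aldh9a1 (-0.84) and Aldh1a3 (-0.75). Aldoc (-0.86), Bpgm (-0.81) and Pfkm (-0.75) also fell, and Adh1 and Pgam2 (1.23) rose. Camera did not call the hypoxia and glycolysis list fixed in advance (adjusted p = 0.111). Larger pathways related to the unfolded protein, NF-kappaB and G2/M lists were not called. Protein processing in the endoplasmic reticulum had 9 of 147 genes rising and 12 falling (camera adjusted p = 0.957). NF-kappaB signalling had 2 of 72 rising and 4 falling (camera adjusted p = 0.995). The cell cycle had 8 of 113 rising and 11 falling (camera adjusted p = 0.952). Antigen processing was higher, with 9 of 49 genes rising, among them the MHC class I genes H2-Q10 (2.10), H2-Q7 (1.72) and H2-Q4 (1.44), which are close relatives and can share reads (camera adjusted p = 0.0406).

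Beside Fos and Fosb, 4 of 26 immediate-early genes rose, namely Ier2 (1.26), Zfp36 (1.14), Nr4a2 (1.08) and Klf4 (0.70), and Srf fell (-0.73). Egr1 (1.82, edgeR adjusted p = 0.0720), Jun (1.29, adjusted p = 0.117) and Myc (0.95, adjusted p = 0.0716) did not pass. A candidate explanation is that immediate-early genes rose as a class. The 26 genes without Fos and Fosb had a median of 0.28 and a camera p of 0.0045, which met the bound set for that explanation, but p was 0.196 with an estimated correlation, so the question stays open.

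Of the 10 ways to part the 6 libraries into 3 against 3, 1, the real one, gave as many genes as 1847, and the highest of the others gave 2. These are too few splits for a share under 0.05. Each other split also puts 2 libraries of 1 group with 1 of the other. Part of the real difference stays in it, so its counts do not stand for chance alone. For the lists, 3 of the 10 splits gave as many as the real 12, and the highest of the others gave 16, so that a count of lists past camera with a preset correlation separates the real groups poorly from other splits. The real split gave the smallest camera p for the G2/M, interferon, cholesterol, unfolded protein, NRF2 and mitochondrial lists. For the mitochondrial and unfolded protein lists the lowest p of another split came close, at 4.78e-07 against 3.99e-07 and 8.1e-07 against 5.87e-07. Other splits gave a camera p as small for the remaining 6 called lists, in 4 of 10 splits (the real one included) for G1/S, NF-kappaB and alveolar type 2 genes, in 3 for secreted factors and in 2 for alveolar type 1 and transitional markers.

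Interferon-stimulated genes had a median of 0.97 in p21 over control cells. Removing trends with gene length and GC content left the median at 1.01 (0.968 before), and leaving out 1 library left it at 0.86 or more, which argues against a length or GC bias and a single library. Leukocytes in the p21 cultures have no source in the design, since MLE-12 is an epithelial cell line. The 12 leukocyte markers tested summed to 11.1 CPM in control and 8.57 CPM in p21 cells. The upper 95% bound of their mean log2 fold change, taken over genes rather than samples, was -0.0904. That bound was -0.267 to 0.454 without 1 library, each below the interferon median. Only 3 of the 12 reach 1 FPKM, and the median of the 13 tested without control replicate 3 was 0.319, so markers this low exclude nothing. A difference in dose or preparation between the vectors cannot be told apart from an effect of p21, since 0 rows of the table are vector or viral sequence and each group received 1 vector. An effect of p21 on these genes may be a further explanation and stays a hypothesis.

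Cholesterol synthesis and NRF2 genes had medians of -0.72 and -0.66. Removing length and GC trends left them at -0.789 and -0.701 (-0.736 and -0.705 before, on the same scale), and leaving out 1 library left them at -0.607 and -0.518 or lower. Of 10000 random lists matched on mean expression, 0 had a median as low as the cholesterol list and 0 as low as the NRF2 list, the lowest being -0.438 and -0.449. These values argue against a length or GC bias, a single library and a shift of genes of like expression. The random lists do not weigh chance, because they draw genes independently of each other. Genes of the cholesterol and NRF2 lists had estimated correlations of 0.257 and 0.482. Vector dose or preparation was not measured here and stays open beside an effect of p21, which may be the source as a hypothesis only.

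G2/M genes were lower than G1/S genes by a difference of medians of -0.462. The difference was -0.449 after removing length and GC trends (-0.403 before, on the same scale) and -0.363 at its closest to 0 with 1 library left out, which argues against a length or GC bias and against a single library. The falling G2/M genes with cyclin E genes that rose are consistent with fewer cells reaching mitosis while the genes of S-phase entry stay expressed, a hypothesis for which phase fractions of the cells were not measured here. MLE-12 cells carry a viral T antigen that binds the retinoblastoma proteins, as background; its level was not measured here, and vector dose stays open for this pattern too.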
